A study of Mus musculus with 6 samples.

How the data were processed

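Dorsal root ganglia hold the cell bodies of the sensory neurons that serve body and limbs, together with satellite glia, Schwann cells, vessels and immune cells. Messenger RNA was sequenced from ganglia of mice 6 months old. The control group carried loxP-flanked (floxed) alleles of Kif2a on both chromosomes, and the knockout group carried the same alleles plus Cre recombinase driven by Avil, a gene of sensory neurons. Each group had 3 libraries, numbered 1 to 3 in the labels, and the labels alone set the groups. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

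Per the labels' protocols, RNA was extracted with TRIzol, its poly(A) fraction was purified and fragmented, and double-stranded cDNA was ligated to adapters and amplified by PCR. Whether the libraries kept strand information is not given in the sources used here, so reads of genes that overlap on opposite strands were not told apart. Per the submitters' processing notes, cutadapt, STAR and DESeq2 were used with the mouse build mm10. The counting tool, the gene annotation and the versions are not given in the sources used here.

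The authors deposited 1 table with 16613 genes, by symbol. Raw counts per gene and library are in it per the file headers, and they were whole numbers when checked. The smallest total over the 6 libraries was 6 counts, so genes below that had been removed. The table also has the authors' normalized signal, which was each raw count divided by 1 size factor per library when checked against the counts, and the mean of these. Per the file headers, it further holds the authors' log2 fold changes, their p-values and a false discovery rate computed with fdrtool. A set of 6 per-library columns of transformed values was not used. No gene name occurred more than once. Mitochondrially encoded genes were not among the rows analysed here.

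The libraries held 18144713, 17118610 and 17604419 counts in control replicates 1 to 3, and 19221415, 16852636 and 16090726 counts in knockout replicates 1 to 3. The most abundant gene took at most 0.81% of a library. At this depth, 3 counts correspond to 0.156 to 0.186 CPM, the count scaled to the library total. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 11.3 to 51.4 over genes, so none was counted as a repeat of another. Counts from Y-linked genes were present in all 6 libraries and Xist had at most 6 counts, so the animals' sex did not separate the groups.

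Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which kept 15043, and libraries were scaled by the trimmed mean of M values (TMM). Dispersions and a robust quasi-likelihood model were fitted to the 6 libraries with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Values per library are TMM-scaled CPM, with the SD over the 3 libraries of a group. Log2 fold changes are knockout minus control, each with its standard error (SE). This model, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined.

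The groups share replicate numbers, so it was checked whether same-numbered libraries deviate together from their group means. Over 15043 genes, Pearson's correlation of these deviations was 0.53, 0.30 and 0.17 for pairs 1, 2 and 3, and in this version every library correlated best with the library of its own number. In the other 3 versions knockout replicate 3 correlated better with control replicate 2 than with control replicate 3. The values were 0.25 against 0.18 (Spearman), 0.35 against 0.22 (Pearson, 8755 genes with a mean log2 CPM above 4) and 0.18 against 0.16 (Pearson, without the muscle, adipocyte and erythroid lists). So pair 3 is the least certain. All same-numbered pairs exceeded 0.1 in each version, the level above which the numbers were taken to pair the samples, and this was settled before the calls of the fits were compared. Control replicate 2 and knockout replicate 3 also exceeded 0.1 in each version (0.14 in the first). That level alone therefore does not tell a same-numbered pair from another. The labels do not say what the numbers share, so the pairing comes from the data. A fit with the replicate number as a block was planned as an alternative, and its values are printed for each result whose call it changes. Throughout, "rose" and "fell" are used of genes that passed the adjusted threshold in this blocked edgeR fit. Log2 fold changes and SEs given with these words are from the blocked fit. No gene passed in the edgeR fit without a block, so every such call rests on the pairing. Values of genes that did not pass are mostly from the fit without a block, so neighbouring SEs can come from different fits.

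Alternatives were DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1, prior count 2 for log2 CPM), other scalings, other filters, an adjusted threshold of 0.1 and leaving out each library. Further blocked fits with other tools, scalings and filters, with each pair left out, or with the trend of log2 fold change on exonic length removed, were added after seeing the data. Lists of genes for cell types, pathways and gene families were tested with camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives, adjusted over the 27 lists tested. Of the 29 lists fixed, the mitochondrially encoded genes could not be tested and the sex-chromosome genes served only as a sample check.

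The rule named Kif2a and Avil in any case. It then took the 12 largest rises and the 12 largest falls among genes with adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups, and up to 4 passing members of each list. Where fewer than 10 genes passed in a direction, it took the genes of smallest unadjusted p up to 6, and for a list with none passing its 2 members of smallest p, as values only. Predicted genes without a proper symbol were counted and not named. Some genes that the rule names are not reported here. Mrgprb5, Mrgpra3, Scn10a, Npy, Sox11, Sdc1 and Plaur fall outside the rule and were chosen after their values were seen. Applying the same rule to the blocked fit was a choice made after seeing the data.

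Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 denotes, in which 15968 of the deposited symbols (96.1%) were found once. The fits were tested on simulated counts for 15043 genes with 200 genes changed. With simulated pair effects, edgeR without a block recovered 0%, 20.9% and 87.9% of genes changed 1.5, 2 and 4-fold, and with the block 17.9%, 56.7% and 93.9%, with 7 of 119 calls false. With no pair effects, the fit without a block recovered 10.4%, 62.7% and 90.9%, with 17 of 126 calls false, and the blocked fit 9%, 59.7% and 92.4%, with 23 of 130 calls false. With simulated pair effects, the fit without a block had 1 of 73 calls false. So in both fits a larger share of calls was false where the numbers pair nothing. In that setting the blocked fit made more false calls than the fit without a block (23 against 17). Each setting was simulated once, with dispersions estimated from the data without a block. A simulated 1.5-fold rise of the macrophage list gave a camera adjusted p of 1.5e-10, and 0 of the 26 other lists were called. Genes were simulated independently of each other, so this run does not test the preset correlation of 0.01 or the list calls that rest on it. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.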

Results

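The transcriptome of dorsal root ganglia was compared between 3 control libraries, from mice with floxed Kif2a alleles, and 3 knockout libraries, from mice that also carried Avil-driven Cre recombinase. All mice were 6 months old. Library totals ran from 16090726 to 19221415 counts, and 15043 genes were tested.

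Kif2a, a kinesin that depolymerises microtubules, is the gene carrying the floxed alleles. Its level was 105.6, 93.86 and 92.66 CPM in control replicates 1 to 3, and 90.57, 85.69 and 88.52 CPM in knockout replicates 1 to 3. The knockout mean was 90.6% of the control mean, with a log2 fold change of -0.14 (SE 0.10) that did not pass (edgeR adjusted p = 0.957). With the replicate block it did not pass either (adjusted p = 0.284). The values of the groups did not overlap, which chance gives for 10% of genes in a design of 3 against 3. Whole-gene counts do not separate the deleted part of Kif2a from the rest of its transcript, nor neurons from the other cells of the ganglion. Kif2a lies on chromosome 13 from 106958996 to 107022126 on the minus strand, and its exons overlap those of Dimt1 on the other strand.

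Avil encodes advillin, an actin-binding protein of sensory neurons, and its regulatory sequence drives the Cre. Avil was at 1095, 1052 and 1003 CPM in control replicates 1 to 3, and at 517.6, 451.2 and 439.5 CPM in knockout replicates 1 to 3. Its log2 fold change was -1.16 (SE 0.12), with an edgeR adjusted p of 0.084 without the block. With the replicate block Avil fell by 1.16 (SE 0.07), at an adjusted p of 2.39e-05, and it was lower in 3 of 3 pairs. Avil lies on chromosome 10 from 127000709 to 127020994, and its exons overlap those of Tsfm on the other strand.

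**Figure D1:**
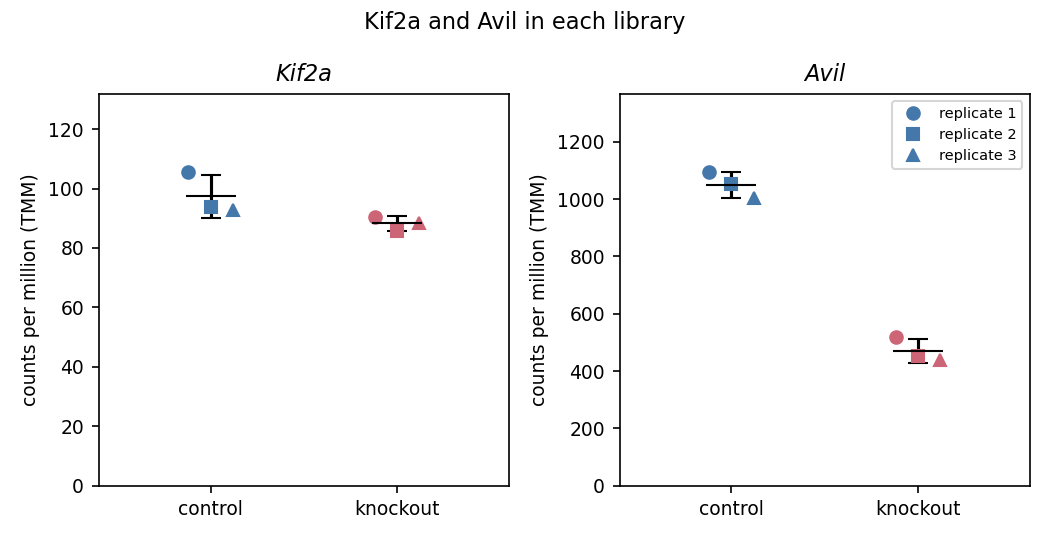
TMM-scaled CPM of Kif2a (left) and Avil (right) in the 3 control and 3 knockout libraries. Symbols are single libraries by replicate number, horizontal lines are group means and error bars are 1 SD (n = 3). Avil is at 439.5 to 517.6 in the knockout and 1003 to 1095 in the control, while Kif2a is at 85.69 to 90.57 against 92.66 to 105.6.

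The series contrasts these groups to ask how loss of Kif2a in sensory neurons bears on nociception. Only the knockout group carried the Cre, and its Avil was lower. Effects of Kif2a loss therefore cannot be told apart here from effects of the Cre or of lower Avil. The genes that fell included Mrgprd, a receptor of non-peptidergic nociceptors, and Sst, the somatostatin gene of itch-related neurons. Mrgprd went from 185.9 ± 26.0 to 79.9 ± 13.3 CPM (SD, n = 3) and Sst from 7.86 ± 4.04 to 2.25 ± 0.87 CPM. Atf3 and Sprr1a are known to be induced in injured sensory neurons. Atf3, a stress-induced transcription factor, went from 9.52 ± 1.24 to 26.4 ± 3.26 CPM, and Sprr1a, a gene of regenerating axons, from 0.434 ± 0.165 to 2.53 ± 0.441 CPM.

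In the fit without a block, 0 of 15043 genes passed an adjusted p of 0.05 in edgeR, and 825 had an unadjusted p under 0.05. The limma-voom and limma-trend tests also called 0 genes, whereas DESeq2 called 63, of which 9 were higher and 54 lower in the knockout. With the replicate block, edgeR called 542 genes, of which 187 rose and 355 fell. Of these, 43 rose and 142 fell by more than 1.5-fold. The blocked count was 208 with pair 1 left out, 819 with pair 2 left out and 897 with pair 3 left out, and 172, 443 and 455 of the 542 genes were among them. The groups did not overlap for 341 of the 542 genes (62.9%), against 11.1% of all tested genes and a chance share of 10%. The 542 genes were selected by a test of the same difference, so a share above chance follows from that selection.

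The 6 genes of smallest p on each side in the fit without a block did not pass, and are given as values. The higher ones were Atf3 (log2 fold change 1.47, SE 0.15), Sprr1a (2.52, SE 0.34), Ecel1 (2.93, SE 0.45), Fosl2 (0.82, SE 0.14), Nts (1.61, SE 0.30) and Tbl1xr1 (0.48, SE 0.10). The lower ones were Avil, Mrgprd (-1.22, SE 0.16), Scn11a (-0.93, SE 0.14), Mab21l1 (-1.55, SE 0.23), Eml1 (-0.75, SE 0.11) and Ptprt (-0.85, SE 0.13). Their adjusted p-values in edgeR ran from 0.084 for Avil and Atf3 to 0.614 for Tbl1xr1. All of them passed with the replicate block, where the adjusted p was 2.39e-05 for Avil and 0.00791 for Tbl1xr1. Mab21l1 shares exonic positions with Nbea, and Eml1 with Gm16596, on the other strand.

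The largest rise in the blocked fit, among genes with a mean of at least 1 CPM, no overlap and a proper symbol, was that of Ecel1. Ecel1, an endopeptidase of injured neurons, had a log2 fold change of 2.97 (SE 0.38, adjusted p = 0.00141). It rested on 3 to 10 counts in the control libraries and 32 to 55 in the knockout libraries. Sprr1a rose by 2.54 (SE 0.32) from 5 to 11 counts in the control libraries. Nts, which encodes neurotensin, rose by 1.64 (SE 0.11, adjusted p = 3.61e-05), from 12.1 ± 4.50 to 37.0 ± 10.1 CPM. Atf3, on chromosome 1 from 191170296 to 191218039, rose by 1.47 (SE 0.11, adjusted p = 7.62e-05). The heat shock genes Hspa1a and Hspa1b rose by 1.14 and 1.09, and since they are near-identical copies the split of reads between them is uncertain. Among genes with a mean of at least 1 CPM, no overlap between groups and a proper symbol, the other large rises were those of Cytip (1.75), Tubb1 (1.72), Sowaha (0.99), Csf3r (0.89), Fosl2 (0.81) and Lrrc17 (0.77). Cytip and Tubb1 had 7 to 13 counts in the control libraries.

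Among genes within the same limits, the largest falls in the blocked fit were those of Fgg, a fibrinogen chain, by 2.0 on the log2 scale (SE 0.27), and of Rspo4, a Wnt-pathway secreted factor, by 1.79 (SE 0.24). Sst, on chromosome 16 from 23889573 to 23890958, fell by 1.77 (SE 0.19, adjusted p = 0.000409). Mab21l1 fell by 1.53 (SE 0.13), from 29.6 ± 9.08 to 10.1 ± 1.62 CPM. Mrgprd, on chromosome 7 from 145314835 to 145324086, fell by 1.22 (SE 0.08, adjusted p = 3.61e-05). Slc9b2, Cyp26c1, Zcchc16, T2, Exph5, Lpar5 and St6gal2 completed the 12 named falls, with log2 fold changes between -1.59 and -1.20. T2 overlaps Gm16702 on the other strand. Among the 24 genes named here by size, 13 kept an adjusted p under 0.05 with each pair left out in turn.

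**Figure D2:**
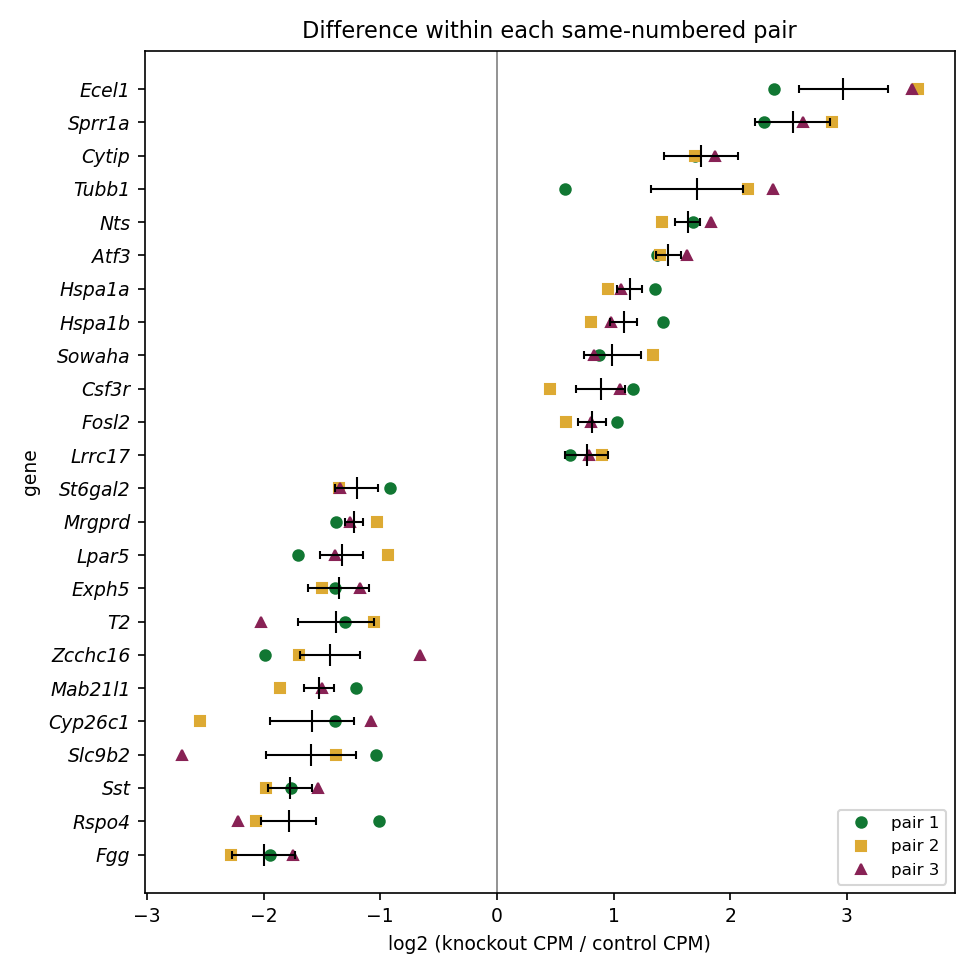
Log2 ratio of knockout to control CPM within each same-numbered pair, for the 12 largest rises and 12 largest falls of the fit with the replicate block among genes with a mean of at least 1 CPM, no overlap between groups and a proper symbol. Symbols are pairs 1 to 3, and black ticks with bars are the fitted log2 fold change ± SE. The 3 pairs of every gene shown lie on the same side of 0, which follows from choosing genes whose groups do not overlap. Fitted values run from Ecel1 at 2.97 to Fgg at -2.0.

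Markers of non-peptidergic nociceptors and pruriceptors, neurons that carry pain and itch signals, were lower as a group. Of the 25 tested, 23 were lower, with a median log2 fold change of -0.84 without the block and -0.86 with it. In the blocked fit 14 fell, among them Sst, Lpar5, Mrgprd and Mrgprb5 (by 1.06, SE 0.19). The sodium channel gene Scn11a fell by 0.93 (SE 0.07), from 639.9 ± 70.1 to 336.6 ± 40.9 CPM, and the purinergic receptor gene P2rx3, which overlaps Ssrp1 on the other strand, fell by 0.78 (SE 0.06). Nts, the 1 member that rose, is also on the injury list. The other 10 did not pass, among them Mrgpra3 at -0.35 (SE 0.12). Adjusted over the list alone, 16 were lower and 1 higher without the block, and 21 were lower and 1 higher with it. The camera adjusted p was 1.5e-20 without the block, and the adjusted p = 0.208 with an estimated correlation did not pass. Leaving out control replicate 2 took the median to -0.59, and the other 5 omissions gave -1.01 to -0.78. Members of the Mrgpr family are similar in sequence, so reads may be split between them.

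Markers of the other neuron classes had medians of smaller size, and the difference between lists was not tested. All 10 tested markers of low-threshold C-fibre mechanoreceptors and cold-sensing neurons were lower, with a median of -0.43, yet 0 passed. Their median was -0.19 without control replicate 2, and -0.59 to -0.31 in the other 5 omissions. Examples are P2ry1 (-0.44, SE 0.21) and Th, the tyrosine hydroxylase gene (-0.61, SE 0.29). Th was at 262.3 CPM in control replicate 2, at 137.1 and 109.1 CPM in control replicates 1 and 3, and at 100.8 to 119.8 CPM in the knockout, and 1 of its 3 pairs was higher. That list had a camera adjusted p of 0.00175, and an adjusted p = 0.254 with an estimated correlation. Peptidergic nociceptor markers had a median of 0.20 over 17 genes, of which Adcyap1, the PACAP gene, rose by 0.38 (SE 0.07). Camera gave this list an adjusted p of 0.0174, and the adjusted p = 0.264 with an estimated correlation did not pass. Without control replicate 3 or knockout replicate 1 the camera call was lost (adjusted p = 0.0928 and 0.112).

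Myelinated mechanoreceptor and proprioceptor markers had a median of 0.17 over 24 genes, and 4 rose. These were Runx3, a proprioceptor transcription factor (0.61, SE 0.14), the neurofilament genes Nefh (0.40, SE 0.07) and Nefm (0.40, SE 0.09), and Ntrk3 (0.39, SE 0.09). The groups overlapped for Nefh and Nefm, whose edgeR adjusted p without the block was 0.914 and 0.957. Nefm overlaps Nefl on the other strand. Camera gave these markers an adjusted p of 0.00175, with an adjusted p = 0.652 with an estimated correlation, and the call was lost without control replicate 2 (0.152) or knockout replicate 1 (0.0993). Pan-neuronal genes had a median of 0.06 over 17 genes and a camera adjusted p of 0.326. Of these, Gap43 and Thy1 rose by 0.34 and 0.31, and Syt1 fell by 0.42.

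**Figure D3:**
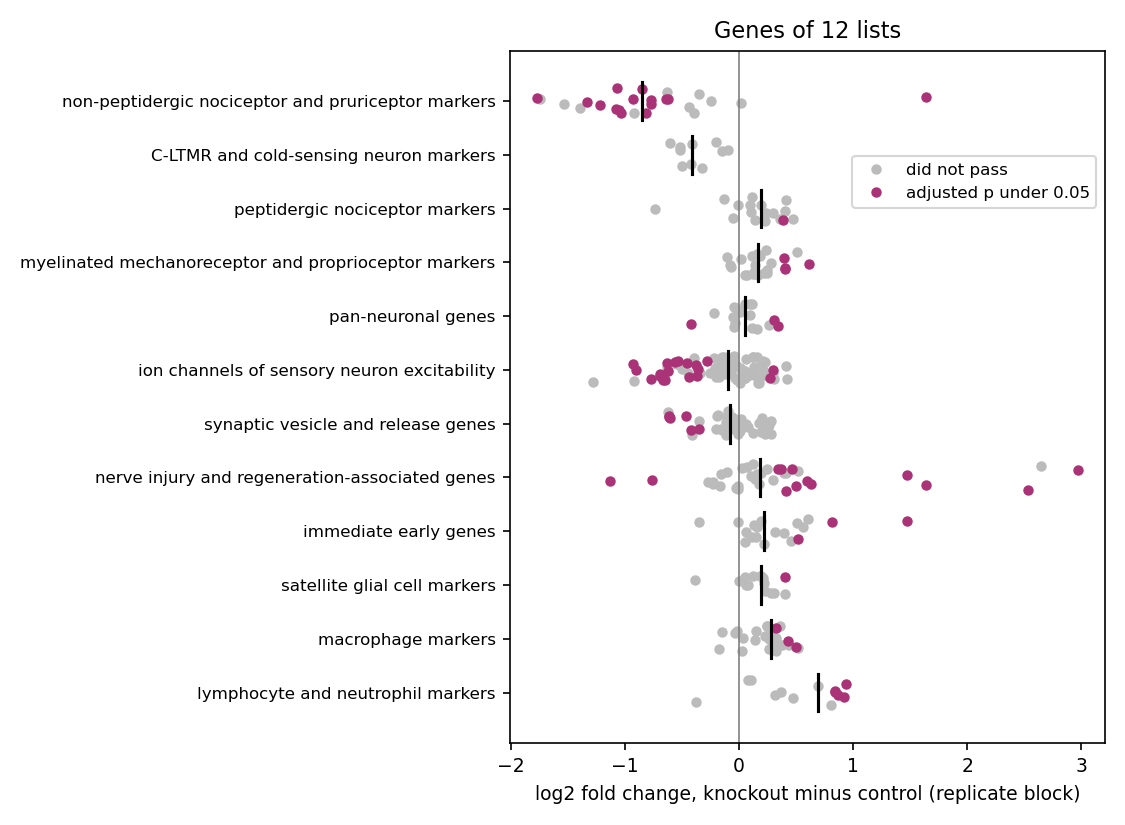
Log2 fold changes (knockout minus control, fit with the replicate block) of the tested genes of 12 lists. Each point is a gene, coloured points had an edgeR adjusted p under 0.05 over all genes, vertical bars are list medians, and vertical scatter within a row has no meaning. The non-peptidergic list has its median at -0.86 and the lymphocyte and neutrophil list at 0.69.

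Ion channel genes of sensory excitability moved in both directions, with 17 of 78 falling and 2 rising in the blocked fit. The falls included Scn11a and P2rx3, which are also on the non-peptidergic list, P2rx2 (by 0.90, SE 0.20) and Kcnk18, a potassium channel gene (by 0.70, SE 0.17). Scn10a, which encodes the sodium channel Nav1.8, fell from 1167 ± 133 to 740.1 ± 129 CPM. Kcnt1, the member with the next smallest p after Scn11a without the block, was at -0.62 (SE 0.13) there and passed with it. The list median was -0.10, with a camera adjusted p of 0.000796 and an adjusted p = 0.652 with an estimated correlation. Without control replicate 1 the median was -0.01 and the camera call was lost (adjusted p = 0.187). Adjusted over the list alone, 1 gene was lower without the block, and 24 were lower and 8 higher with it.

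Genes linked to nerve injury and regeneration had a median of 0.18 over 36 tested members, and 11 rose and 2 fell in the blocked fit. The largest rises were those of Ecel1, Sprr1a, Nts and Atf3, and the falls were those of Sdc1 (by 1.13, SE 0.10) and Plaur (by 0.77, SE 0.16). Npy, a neuropeptide gene induced by axotomy, went from 0.475 ± 0.420 to 2.93 ± 0.564 CPM and did not pass (blocked adjusted p = 0.0558). Sox11 was at 13.7 ± 3.0 and 14.2 ± 0.641 CPM. Adjusted over the list alone, 10 were higher and 1 lower without the block, and 17 and 4 with it. With a library left out, the list median ran from 0.09 (without knockout replicate 1) to 0.30 (without control replicate 1 or knockout replicate 2). The camera adjusted p was 2.39e-06, with an adjusted p = 0.208 with an estimated correlation.

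Immediate early genes, which respond within minutes to stimulation, had a median of 0.19 over 19 genes, and Atf3, Fosl2 and Nr4a1 rose. Nr4a1 went from 30.1 ± 3.67 to 42.9 ± 1.71 CPM. The median ran from 0.11 (without control replicate 2) to 0.44 (without control replicate 3). The camera adjusted p was 2.39e-06, and the adjusted p = 0.386 with an estimated correlation did not pass. Adjusted over the list alone, 3 were higher without the block and 7 with it. Genes of the integrated stress and unfolded protein responses had a median of 0.12 over 27 genes (0.07 to 0.18 with a library left out), of which Ddit4 rose by 0.49 (SE 0.08). Chac1, with a log2 fold change of 0.59 (SE 0.22), did not pass. The camera adjusted p was 0.00237, with an adjusted p = 0.208 with an estimated correlation, and fry gave 0.0353 without the block and 0.0621 with it.

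Among genes of the synaptic release machinery, 6 of 40 fell and 0 rose. The largest falls were those of Syt7 (by 0.62, SE 0.08), Unc13c (by 0.62, SE 0.08), Syt9 (by 0.61, SE 0.08) and the granin gene Scg3 (by 0.47, SE 0.07). The list median was -0.05, with a camera adjusted p of 0.109. That p was 0.00795 without control replicate 2, 0.0255 without control replicate 3 and 0.000276 without knockout replicate 1, where the median was -0.22. Adjusted over the list alone, 2 were lower without the block, and 9 were lower and 9 higher with it. Of the other kinesin genes, 3 of 41 fell, namely Kif23 (by 0.70, SE 0.16), Kif5a (by 0.33, SE 0.07) and Kif5b (by 0.28, SE 0.06). Kif4 was at 0.90 (SE 0.36) without the block and did not pass, and it overlaps Pdzd11 on the other strand. The kinesin list had a camera adjusted p of 0.658.

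Of the tubulins and microtubule regulators, 4 of 70 rose and 3 fell, with a camera adjusted p of 0.899. Dpysl2, which encodes a tubulin-binding protein of growing axons, rose by 0.71 (SE 0.11), and Tubb6 rose by 0.41 (SE 0.09). Dcx, the doublecortin gene, fell by 1.06 (SE 0.14) and Ckap5, a microtubule polymerase gene, by 0.54 (SE 0.07). Among axon guidance and adhesion genes, 4 of 75 fell and 0 rose, with a median of 0.05 and a camera adjusted p of 0.493, both without the block. With a library left out, camera called this list higher without control replicate 1 (median 0.14, adjusted p = 0.00655) and knockout replicate 2 (0.14, 0.0386), and lower without control replicate 2 (-0.09, 0.0347). The 4 genes that fell were Plxnc1 (by 0.64, SE 0.07), Slit1 (by 0.62, SE 0.07), Robo2 (by 0.39, SE 0.09) and Rgmb (by 0.29, SE 0.07). Robo4, a vascular family member, was at 0.51 (SE 0.19) and did not pass.

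Satellite glial markers had a median of 0.20 over 15 genes, of which S100b rose by 0.40 (SE 0.07). Aldh1l1 was at 0.41 (SE 0.15) without the block and did not pass in either fit. Without knockout replicate 2 the median was 0.08 (camera adjusted p = 0.0386), and the other 5 omissions gave 0.15 to 0.22. The camera adjusted p with all libraries was 0.00121, and the adjusted p = 0.386 with an estimated correlation did not pass. Myelinating Schwann cell markers had a median of 0.06 over 20 genes, 0 of which passed, with Cadm4 at 0.23 (SE 0.17) without the block. The Schwann cell list had a camera adjusted p of 0.326, which was 0.0384 without control replicate 3 and 0.0297 without knockout replicate 2.

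Macrophage markers had a median of 0.29 over 27 genes, and C1qb (0.50, SE 0.10), C1qa (0.43, SE 0.10) and H2-Aa (0.32, SE 0.07) rose. For all of these genes the groups overlapped. Without the block their SEs were 0.34, 0.34 and 0.28, and their edgeR adjusted p was 0.957, 0.974 and 0.975. The macrophage list had a camera adjusted p of 0.0174, with an adjusted p = 0.859 with an estimated correlation. It was 0.661 without control replicate 1, 0.431 without knockout replicate 2 and 0.607 without knockout replicate 3. The macrophage median was 0.04 without control replicate 1, 0.07 without knockout replicate 3 and 0.53 without knockout replicate 1. Lymphocyte and neutrophil markers had a median of 0.57 over 13 genes without the block, and 5 rose in the blocked fit, all of them genes of neutrophils. S100a8 and S100a9 rose by 0.94 (SE 0.14) and 0.87 (SE 0.08), Ltf by 0.92 (SE 0.13) and Ngp by 0.84 (SE 0.09). The groups overlapped for Ltf and Ngp, whose edgeR adjusted p without the block was 0.939 and 0.957. That list had a camera adjusted p of 0.00131, with an adjusted p = 0.652 with an estimated correlation, and it was 0.0986 without control replicate 1. The list's median was 0.22 without knockout replicate 3 and 1.06 without control replicate 3. Interferon response and antigen presentation genes had a median of 0.23 over 37 genes, with Rsad2 rising by 0.70 (SE 0.15) and Ifit2 falling by 0.49 (SE 0.10). Their camera adjusted p of 0.013 became an adjusted p = 0.859 with an estimated correlation. It was 0.187 and 0.222 without control replicates 1 and 3, and 0.94 and 0.0892 without knockout replicates 2 and 3. The interferon median ran from 0.00 without knockout replicate 2 to 0.47 without knockout replicate 1.

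Fibroblast and connective tissue markers had a median of 0.07 over 30 genes, of which Lum rose by 0.41 (SE 0.07) and Fbln2 by 0.34 (SE 0.08). The groups overlapped for Lum, which had an SE of 0.34 and an edgeR adjusted p of 0.979 without the block. The fibroblast list had a camera adjusted p of 0.116 without the block and 0.0275 with it, where the adjusted p = 0.705 with an estimated correlation. Without the block it was 3.09e-05 when control replicate 3 was left out and 0.0318 when knockout replicate 2 was. Endothelial and mural cell markers had a median of 0.00 over 22 genes, with Egfl7, which overlaps Agpat2 on the other strand, at 0.30 (SE 0.10) and Pdgfrb at -0.28 (SE 0.12), and 0 passed. For the endothelial list camera gave an adjusted p of 0.675, and 0.00545 without control replicate 3. Of the 3 erythroid genes tested, Slc4a1 rose by 0.76 (SE 0.14), and the camera adjusted p was 0.0533 without the block and 0.0143 with it, where the adjusted p = 0.553 with an estimated correlation. Without the block it was 0.0245 when control replicate 2 was left out and 0.00782 when knockout replicate 1 was.

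Skeletal muscle genes were high in 1 control library. The 16 tested muscle and bone markers summed to 1896.7 CPM in control replicate 2 and to 31.0 to 110.6 CPM in the other 5 libraries. Myh1, a fast myosin gene, had 3896 counts there and 7 to 85 counts elsewhere. The list median was -3.81, with a camera adjusted p of 0.00579 and an adjusted p = 0.689 with an estimated correlation, and 0 genes passed. Without control replicate 2 the median was 0.38 (adjusted p = 0.939). The authors' deposited table gives Myh1 a false discovery rate of 0.00618. Adipocyte markers had a median of -1.31 over 12 genes, none of which passed, with Car3 at -1.58 (SE 0.54) and Pck1 at -1.47 (SE 0.51). Their camera adjusted p was 0.0174 without the block and 0.0525 with it, and the adjusted p = 0.652 with an estimated correlation and no block. It was 0.309 without control replicate 3 and 0.063 without knockout replicate 3. The adipocyte median was -0.5 without control replicate 3 and -1.75 without control replicate 1. Spinal cord and oligodendrocyte markers, of which 8 were tested and 0 passed, had a median of -0.13, with Mobp at -1.21 (SE 0.80), and a camera adjusted p of 0.926.

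Nuclear-encoded oxidative phosphorylation genes had a median of 0.15, with 65 of 72 above 0, and Atp5e rose by 0.33 (SE 0.07). Without the block Atp5e was at 0.34 (SE 0.32), and its groups overlapped. Cox7b was at 0.82 (SE 0.22) without the block and 0.79 (SE 0.33) with it, and passed in neither fit. The camera adjusted p was 0.00128, with an adjusted p = 0.859 with an estimated correlation. Without control replicate 1 the median was -0.01 (adjusted p = 0.88), and the call was also lost without knockout replicate 2 (0.227) or 3 (0.151). In the blocked fit, log2 fold changes fell with exonic length over 14495 genes (Spearman -0.18), with a fitted trend between -0.15 and 0.12. Removing this trend took the median of the 71 oxidative phosphorylation genes of known length from 0.15 to 0.05, with a camera adjusted p of 0.0084.

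Cytosolic ribosomal protein genes had a median of 0.10 over 53 genes, of which Rpl38 rose by 0.29 (SE 0.07). The ribosomal list had a camera adjusted p of 0.109 without the block and 0.00298 with it, where the adjusted p = 0.735 with an estimated correlation. Without the block it was 1.84e-06 when control replicate 2 was left out and 2e-08 when knockout replicate 1 was, with a median of 0.28 in both. Removing the trend on exonic length took the blocked median from 0.09 to 0.02, and the blocked call was lost (adjusted p = 0.258). Their summed level ran from 7970.6 to 12511.8 CPM over the 6 libraries, and replicate 1 was the lowest in both groups. Cholesterol synthesis genes had a median of 0.09 over 24 genes, 0 of which passed. Without the block Cyp51, which overlaps Akap9 on the other strand, was at 0.25 (SE 0.11) and Mvd at 0.27 (SE 0.14). The cholesterol list had a camera adjusted p of 0.0278, with an adjusted p = 0.752 with an estimated correlation, and 4 of the 6 fits with a library left out lost the call (0.143 and 0.533 without control replicates 1 and 3, and 0.133 and 0.0746 without knockout replicates 1 and 2).

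Over all 27 lists, camera called 16 without the block, 11 higher and 5 lower, and 18 with it. With an estimated correlation it called 0 in either fit. Of the 16, 6 kept their call and direction whichever library was left out. These were the non-peptidergic, low-threshold C-fibre, injury, immediate early, stress response and satellite glial lists, whose medians nevertheless moved as given above.

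The authors' deposited table gives 141 genes a false discovery rate under 0.05, of which 35 were higher and 106 lower in the knockout. It marks 106 of them as also past 1.5-fold, while an exact 1.5-fold threshold on the deposited values gives 105. The mark differs from that threshold for 3 genes, and the authors' exact threshold is not given in the sources used here. Of the 141 genes, 128 also passed in the blocked edgeR fit, and all 138 of those tested there had the same direction. Of the authors' p-values, 54.5% were above 0.5, against 34.4% in the blocked fit and 49.1% in the fit without a block.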

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

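Blocked fits other than the planned edgeR fit were chosen after seeing the data. The count of 0 genes without a block was also 0 under the other scalings and filters, limma-voom, limma-trend and each omission of a library (range 0 to 0). It was 2 at an adjusted threshold of 0.1, 63 in DESeq2 and 141 in the authors' deposited table, and past 1.5-fold DESeq2 gave 58 and the authors' values 105. With the replicate block it was 542, and 185 past 1.5-fold. Other blocked fits gave 416 (DESeq2), 567 (limma-voom), 552 (limma-trend), 538 (DESeq2 size factors), 521 (upper quartile), 504 (library totals) and 542 (no filter). Past 1.5-fold these were 143, 195, 188, 186, 177, 179 and 193. With pair 1, 2 or 3 left out, the blocked counts were 208, 819 and 897, and 154, 272 and 280 past 1.5-fold. Renumbering the libraries, as given under the other observations, bears only on the difference between 0 and 542 calls. All 63 DESeq2 calls were among the authors' 141, and 54.6% and 54.5% of the p-values were above 0.5. These 2 counts differ in the adjustment, as the authors' false discovery rate was computed with fdrtool. The cause of the other differences was not tested.

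Kif2a stayed lower and did not pass under every alternative run, with log2 fold changes of -0.18 to -0.09. Avil stayed between -1.24 and -1.12 with a library left out, and passed in none of these fits (lowest edgeR adjusted p = 0.112). It passed at -1.16 in DESeq2, in the authors' deposited table and in the replicate block fit. The other blocked fits gave Avil -1.17 (DESeq2), -1.16 (limma-voom), -1.16 (limma-trend), -1.22, -1.13 and -1.15 (pair 1, 2 or 3 left out), -1.16 (DESeq2 size factors), -1.15 (upper quartile), -1.16 (library totals) and -1.17 (no filter). All 101 named genes kept their sign in every fit. In the blocked fit 73 of them passed, and 33 of these passed with each pair left out in turn. The rule applied to the blocked fit named 68 of the 101, so their passes there follow from that choice. Most of the others were named for a small p in the same libraries, and the fits share libraries. The constant signs are therefore no independent check.

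Camera called 16 of 27 lists, 11 to 18 with a library left out. With an estimated correlation it called 0, and fry called 1. With the replicate block, an estimated correlation gave 0 and fry gave 2. The non-peptidergic median of -0.84 lost its call with an estimated correlation (adjusted p = 0.208) and in fry (0.0912), and at -0.86 in the replicate block with an estimated correlation (0.303), but kept it in fry with the block (0.013). The injury median of 0.18 lost its call with an estimated correlation (0.208; 0.519 with the block) and in fry (0.0582; 0.0621 with the block). Of the other lists called by camera, these medians lost the call with an estimated correlation and in fry, without and with the replicate block: peptidergic 0.20 and 0.19, low-threshold C-fibre -0.43 and -0.42, myelinated 0.17 and 0.16, ion channel -0.10 and -0.10, satellite glial 0.20 and 0.19, macrophage 0.29 and 0.28, adipocyte -1.31 and -1.15, muscle -3.81 and -2.21, interferon 0.23 and 0.21, immediate early 0.19 and 0.22, oxidative phosphorylation 0.15 and 0.15, cholesterol 0.09 and 0.09. The lymphocyte and neutrophil list (0.57 and 0.69) kept it in fry with the block, and the stress response list (0.12 and 0.12) in fry without it.

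With 1 library left out, list medians whose sign or camera call varied ran from -0.04 to 0.10 (pan-neuronal), 0.14 to 0.22 (peptidergic), 0.12 to 0.22 (myelinated), -0.26 to -0.01 (ion channel), -0.04 to 0.18 (Schwann), 0.04 to 0.53 (macrophage), 0.22 to 1.06 (lymphocyte and neutrophil), -0.11 to 0.16 (endothelial), -0.04 to 0.30 (fibroblast), -1.75 to -0.50 (adipocyte), -5.48 to 0.38 (muscle), -0.44 to 0.15 (spinal cord), 0.19 to 0.65 (erythroid), -0.07 to 0.06 (kinesin), -0.12 to 0.07 (tubulin), -0.09 to 0.14 (axon guidance), -0.22 to 0.10 (synaptic), 0.00 to 0.47 (interferon), -0.01 to 0.31 (oxidative phosphorylation), 0.05 to 0.17 (cholesterol) and -0.06 to 0.28 (ribosomal). A call turned in direction or ended with a turned median for the muscle list at 0.38 and the axon guidance list at -0.09, both without control replicate 2, and for the oxidative phosphorylation list at -0.01 without control replicate 1. These fits hold fewer libraries, and the cause was not tested further.

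With the replicate block, list medians whose sign or camera call differed from the fit without it were fibroblast 0.09, adipocyte -1.15, erythroid 0.33 and ribosomal 0.09. With pair 1 left out they were endothelial -0.04, spinal cord 0.08, erythroid 0.34, synaptic -0.09, cholesterol 0.07 and ribosomal 0.14. With pair 2 left out they were satellite glial 0.09, endothelial -0.08, fibroblast 0.11, adipocyte -0.95, muscle 0.78, spinal cord 0.12, erythroid 0.57, kinesin 0.01, tubulin 0.02, interferon 0.23 and ribosomal 0.16. With pair 3 left out they were peptidergic 0.09, endothelial 0.19, fibroblast 0.21, adipocyte -0.30, erythroid 0.26, tubulin 0.01, axon guidance 0.10, interferon 0.01 and cholesterol 0.05. Upper-quartile scaling put the kinesin median at 0.01 and the tubulin median at 0.00, and library totals put the kinesin median at 0.00. The block changed the camera call of 4 lists, each given above, and of no other. In the replicate block fit with the trend on exonic length removed, camera called 18 lists. The medians that differed in sign or call from the fit without a block were fibroblast 0.10, erythroid 0.28, endothelial -0.01 and kinesin 0.00. The ribosomal list at 0.02 then lost the call that the block had given it.

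A sex covariate was not run, because all 6 libraries had Y-linked counts, and pseudocounts did not apply to counts. Genes under about 10 counts per library, such as Ecel1 and Sprr1a in the control, limit the precision of their folds.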

Other observations

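The lists in these opening paragraphs were picked after seeing the data, from genes seen to change, so their counts and medians only describe and no list test is given. The renumbering of the libraries was added after the data were seen, with its prediction written before its result. Predictions written after the values were seen are those for the tests of neuron share, of values per library, of exchanged libraries and of the remaining Kif2a reads. The 12 tested genes that respond to glucocorticoids had a median log2 fold change of 0.39 in the blocked fit, and 7 rose, among them Tsc22d3 (0.36, SE 0.07), Sgk1 (0.45, SE 0.09), Mt1 (0.43, SE 0.08) and Mt2 (0.52, SE 0.12). Output genes of the circadian clock had a median of 0.42 over 10 genes, and Per1 (0.72, SE 0.12) and Dbp (0.68, SE 0.15) rose. Genes of the opposite clock phase, such as Arntl, had a median of -0.16 over 5 genes and 0 passed. Of 11 heat shock genes 4 rose, namely Hspa1a, Hspa1b, Hspb1 and Bag3.

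Genes of neutrophils and their precursors had a median of 0.86 over 14 genes, and 9 rose. Examples are Retnlg (1.24, SE 0.22), Lcn2 (1.11, SE 0.14), Chil3 (1.06, SE 0.19) and Mpo (0.84, SE 0.19). Of the 9, Mpo, Ngp, Ltf, S100a8 and S100a9 were already counted on the lymphocyte and neutrophil list, and Csf3r was named above by size. Platelet and megakaryocyte genes had a median of 0.44 over 8 genes, of which Tubb1 rose, and cell cycle genes a median of 0.38 over 16 genes, of which Mki67 rose by 0.60 (SE 0.14).

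The blocked fit called 542 genes and the fit without a block 0. Renumbering the control libraries in the other 5 ways gave at most 20 calls. Variation shared by same-numbered libraries, such as a shared day or litter that the labels do not record, would give this pattern. The same counts had already shown same-numbered libraries to deviate together, so the renumbering is not independent of that check. With so few numberings, the labels' own could also come first by chance. Of the 4 splits that part all 3 pairs, 1 gave as many blocked calls, the real one, and the highest other gave 0. Without the block, 10 of the 10 splits of the 6 libraries gave at least the real count of 0, and the highest other gave 2. Both sets of splits are too few for a share under 0.05.

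The markers of non-peptidergic neurons had a median log2 fold change of -0.86 with the block. A lower share of neurons would lower pan-neuronal genes too, but their median was 0.05 (bootstrap 95% interval -0.05 to 0.11). The bootstrap resampled the 17 genes and not the libraries, so its interval holds no spread between samples. With 1 library left out, the pan-neuronal median without the block ran from -0.04 to 0.10. Removing the trend on exonic length left the list's median at -0.82. The median of -0.59 without control replicate 2 missed the bound of -0.6 set beforehand for excluding a single library. That explanation therefore stays open. For 64% of the list's genes the groups did not overlap, so the direction of these genes did not rest on 1 library. That share counts both directions and includes Nts, which was higher in the knockout. The chance share of 10% holds for a single gene. It cannot be set against correlated list members (estimated correlation 0.305 without the block). A biological candidate explanation is fewer of these neurons, or lower expression in them, in the knockout, and these cannot be told apart in whole-ganglion RNA. It was not tested and stays a hypothesis, as the call also depends on the correlation assumed between genes and deciding it would need counts of these neurons in tissue or data from single cells.

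Kif2a stayed at 90.6% of the control level while Avil was at 44.7% of it. Mislabelled or exchanged libraries stay open, since the lowest control value of Avil was 1.94 times the highest knockout value but groups exchanged as a whole would be separated alike, and Kif2a does not mark the knockout libraries. Fewer neurons as the cause of lower Avil are argued against by the pan-neuronal median of 0.05. Kif2a reads from cells without Cre, or from exons outside the deleted part, may account for its level, and whether they do cannot be told apart from incomplete deletion with counts per whole gene. Loss of 1 Avil allele to a Cre insertion is a candidate explanation of the lower Avil that was not tested, as the labels do not describe the Cre allele, and genotyping or reads told apart by allele would decide it.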
